A study of Arabidopsis thaliana with 6 samples.

How the data were processed

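Transcript levels were measured in root tips of 7-day-old Arabidopsis seedlings grown in darkness, after 1 h of red light or 1 h of further darkness. Each group held 3 samples that the labels call biological replicates, and each sample was hybridised to 1 single-colour Affymetrix array. Per the labels, tissue from several plates was pooled for each sample, RNA was reverse transcribed from an oligo-dT primer, and the transcribed cRNA carried biotin. The starting amount was 5 µg of total RNA. The authors deposited 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its detection calls and the array design's build were not given in the sources used here. In the deposited intensity values the mean after trimming 2% from each end lay between 500.04 and 500.06 on every array, so each array had been scaled by 1 factor, without equalising the shape of the distributions. The array medians ran from 150 (dark 1) to 176.4 (dark 2).

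From the 22810 probe sets, 64 control probe sets were set aside, which left 22746. Values were taken as log2 without a pseudocount, and no value was 0. Probe sets whose mean log2 value over all arrays lay above the 40th percentile, a signal of 88.4, were tested, which left 13647. A single-colour MAS5 value near the floor is noisy on the log scale, so this filter changes which genes can be called. Each probe set was fitted with limma 3.58.1 (lmFit, eBayes with trend and robust, statmod 1.5.0) in R 4.3.3, with group as the only term, as red light minus dark. P-values were adjusted by Benjamini and Hochberg, 2-sided, with a threshold of 0.05. The number of arrays, 3 per group, limits the precision, and the median standard error of a log2 change was 0.38.

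Gene names came from the platform annotation of the array, with symbols updated through a RefSeq gene table (TAIR10.1) used for names only. That annotation gave exactly 1 gene for 13513 of the 22746 probe sets and several genes for 503, and did not list 8730. Of the 13513, 13436 had a locus tag in the RefSeq table. Probe sets that were not listed or matched several genes are unnamed here, but they were filtered and fitted like the rest. The 23 gene lists covered light, hormone, stress, photosynthesis and tissue marker genes. Of their 382 distinct genes, 47 had a named probe set and 35 were tested through one. A listed gene counts as tested only through a named probe set, and further ones may lie among the unnamed probe sets. Lists with at least 3 tested members, 6 of the 23, were tested with camera (limma, preset correlation 0.01), adjusted over these lists, and again with the correlation estimated and with fry. The other 17 lists had fewer tested members, and single genes are reported only from those with any. Several had 0 tested members, among them the photoreceptors and light-signalling repressors (23 genes) and the light-induced regulators (21 genes). Those lists could not be examined through named probe sets.

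The naming rule took called genes with groups that did not overlap, and, where fewer than 5 qualified in a direction, the 8 genes with the smallest p in that direction. It also took the 2 members with the largest absolute moderated t in each list described, and all 3 root hair markers. AT2G43590, AT2G39210 and AT4G15390 lie outside that rule, since they were called only with array class, and were named after their values were seen. A further 6 light-response genes that the rule always names had no named probe set. Any unnamed probe sets of these genes that passed the filter were fitted, but could not be identified here. The lists, the test, the naming rule and the main set of alternatives were fixed before the data were examined. Taking 2 list members, within a planned limit of 4, was settled afterwards.

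The control probe sets showed afterwards that the arrays fell into 2 classes by the 3'/5' signal ratio of the GAPDH transcript. Dark 1, dark 3 and red light 1 formed the class with a high ratio, and dark 2, red light 2 and red light 3 the class with a low ratio. Each class held arrays of both groups. A second limma fit with array class as a term beside group was therefore added after the data were seen, and its values are given with the class named. It left 3 residual degrees of freedom in place of 4. The change was also taken within each class, 1 array against 2 in each.

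Both fits were tested on simulated data with 200 of the 13647 probe sets changed, in 5 simulations of the red light comparison. With the class difference simulated, the fit by group alone recovered 0% of changes of 1 on the log2 scale and 0% of changes of 2. The fit with array class recovered 4.4% and 50.4%, with a mean of 1.4 false calls. Without a class difference the fit by group alone recovered 23.2% and 70.0%. Camera, run with array class in the fit, called 20 of 20 simulated lists of 8 genes shifted by 1 on the log2 scale and 0 of 20 lists without a shift. The simulated genes varied independently, and most of the tested lists were shorter. The result therefore does not carry over to lists whose genes vary together.

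Alternatives covered the scaling (quantile, 75th percentile), a pseudocount of 32, the filter (none, 60th percentile), the replicate number as a block, array weights, plain eBayes, thresholds of an adjusted p of 0.1 or a log2 change of at least 1, and each array left out. Added after the data were seen were array class, the GAPDH ratio as a covariate, the GAPDH, actin or ubiquitin ratio beside array class, the low-ratio class alone, families of genes that share a symbol stem, and the chloroplast-encoded and mitochondrially encoded genes. No coordinates are reported, since no genome of a stated build was used.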

Results

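The data comprised 6 arrays from 1 cm root tips of dark-grown Arabidopsis seedlings, 3 after 1 h in red light of 12 to 14 µmol per square metre and second (peak 630 nm) and 3 kept in darkness. The comparison asks which transcripts in roots respond within 1 h to red light. Of the 22746 probe sets that are not controls, 13647 were bright enough to be tested. All values are MAS5 signals, with changes given as red light minus dark on the log2 scale.

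In red light the chloroplast transcript psaB, which encodes a core protein of photosystem I, rose by 2.91 (SE 0.40, 7.50-fold, n = 3 arrays per group, limma adjusted p = 0.0224 with array class in the fit). Of the 43 tested chloroplast-encoded genes, 38 had a change above 0 in that fit. More organelle RNA in the red light targets therefore stays open as a source for psaB too. The nuclear genes AT1G13670 and AT3G02910 rose as well in that fit, by 2.54 (SE 0.39) and 1.68 (SE 0.25). AT5G23830 fell by 5.19 (SE 0.38, 36.5-fold, limma adjusted p = 0.00016). AT2G43590, of the chitinase family, fell by 2.53 (SE 0.31), ZW9 fell by 2.45 (SE 0.35), AT2G39210 fell by 1.68 (SE 0.27) and AT4G15390, of an acyltransferase family, fell by 1.32 (SE 0.20). These calls came from the fit with array class, which was chosen after the data were seen, and AT2G43590, AT2G39210 and AT4G15390 were named from it alone. With group alone, limma called 0 probe sets. With array class, AT5G23830 stayed called in every alternative that tested it (limma adjusted p of 1.01e-05 to 0.00739). The call of psaB was lost without red light 2, red light 3 or dark 3, with plain eBayes, with a replicate block and with the GAPDH ratio added (range of 0.000823 to 0.317). Of the others, AT2G43590 lost its call in 3 of 18 alternatives, AT3G02910 in 6 of 18, AT1G13670 in 7 of 17, ZW9 in 7 of 18, and AT4G15390 and AT2G39210 in 9 of 18 each. All 6 lost it with plain eBayes and with the GAPDH or actin ratio added, and all but AT2G43590 without red light 2 or red light 3.

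Every one of these 8 genes moved the same way within both array classes. The fit that called them favours changes shared by both classes, so this is no separate support. Each class also compares 1 array with 2. The change of psaB was 2.00 in the class with a high 3'/5' ratio and 3.81 in the class with a low ratio. AT5G23830 changed by -4.57 and -5.81 there, AT1G13670 by 1.83 and 3.25, and AT3G02910 by 1.20 and 2.17. The signal of AT5G23830 was 457.3, 2768 and 482.7 in the dark and 19.8, 37.1 and 65.6 in red light, for replicates 1, 2 and 3. For AT2G43590 and AT2G39210 the signals of the groups overlapped. Both also differed between the classes, by -3.05 and -2.92 in the high-ratio class against the low-ratio class. AT5G23830, AT3G02910, ZW9 and AT4G15390 differed between the classes as well, by -1.94, -1.49, -0.99 and -0.90. All of these passed the threshold for class in limma, whereas psaB (0.13) and AT1G13670 (0.11) did not.

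**Figure D1:**
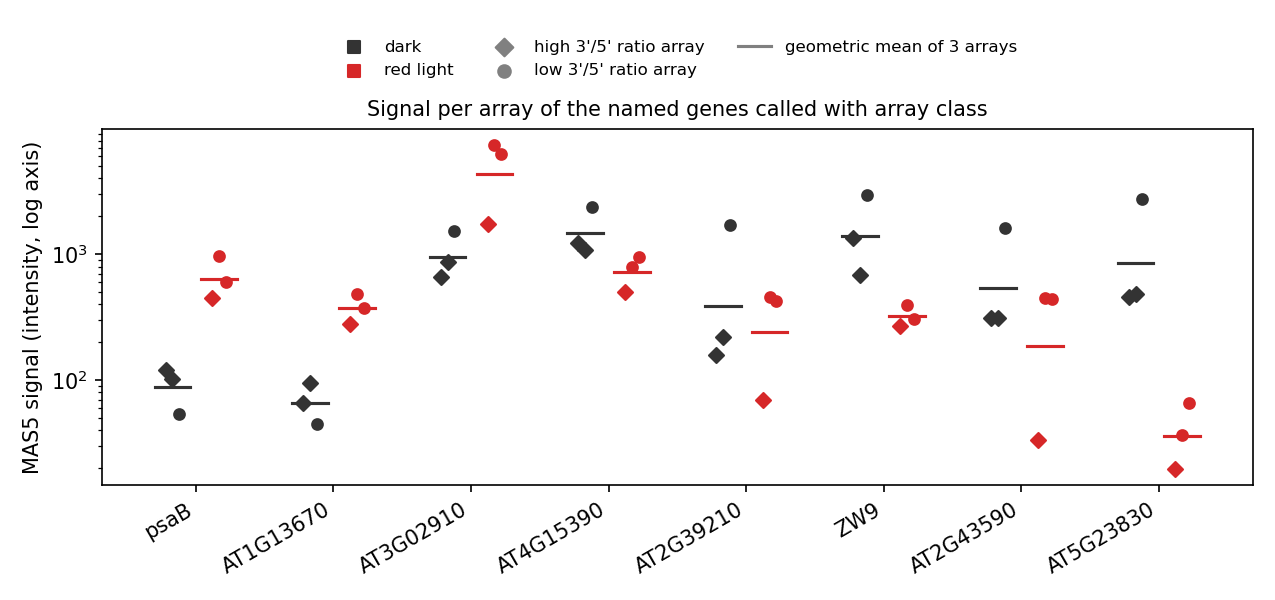
MAS5 signal (vertical log axis) of the 8 named genes called with array class in the fit, with 1 point per array, dark in black and red light in red, diamonds for high-ratio and circles for low-ratio arrays, and bars at the geometric mean of 3 arrays. The psaB signals were 54.4 to 120.7 in the dark and 446.3 to 968 in red light, whereas the AT2G43590 groups overlapped.

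In all, the fit with array class called 17 probe sets, 11 higher and 6 lower in red light, and 15 of these showed no overlap between the groups. The count depended on the fit and the arrays, with 5 under plain eBayes, 7 with the GAPDH ratio added, 8 without red light 2, 9 without red light 3, 71 without red light 1 and 272 without dark 2. The 8 named genes account for 3 of the higher and 5 of the lower probe sets, and the other 9 are unnamed here. One of the unnamed probe sets had the smallest adjusted p in limma, 7.56e-05, and rose by 4.55 (SE 0.29), from signals of 132.3 to 177.5 up to signals of 1748.9 to 6227.2. Others rose by up to 3.78 (SE 0.35), and the single unnamed probe set that was lower fell by 3.06 (SE 0.45).

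With group as the only term, the planned test, limma called 0 of 13647 probe sets, and the smallest adjusted p was 0.196. An unadjusted p under 0.05 was reached by 258 probe sets, where 682 would be reached by chance. The signals of the groups did not overlap for 841 probe sets, 6.16% of those tested, against 10% by chance. Both chance values take the arrays as interchangeable, whereas the array classes cross the groups. Neither shortfall therefore speaks for or against a response to red light. Of the 17 probe sets called with array class, 14 had an unadjusted p under 0.05 with group alone. In the fit with array class, 939 probe sets reached an unadjusted p under 0.05, above the 682 by chance. That excess was not tested.

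The arrays differed by class far more than by treatment. The 3'/5' signal ratio of GAPDH was 26.2 in dark 1, 20.2 in dark 3 and 20.9 in red light 1, but 1.45 in dark 2, 0.981 in red light 2 and 1.27 in red light 3. The ratio of actin was 71.7, 90.7 and 138 against 15.3, 13.8 and 20.9, in the same order of arrays. The ratio of ubiquitin was 8.73, 6.95 and 8.79 against 1.66, 1.47 and 1.81. The bacterial and phage spike-in transcripts BioB, BioC, BioD and Cre were 4.01 to 4.79 times as bright in the high-ratio class. With group in the fit, limma called 5020 probe sets different between the classes, 2034 higher and 2986 lower in the high-ratio class. Across probe sets, Pearson correlations between arrays were 0.917 to 0.965 within a class and 0.761 to 0.865 between classes.

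**Figure D2:**
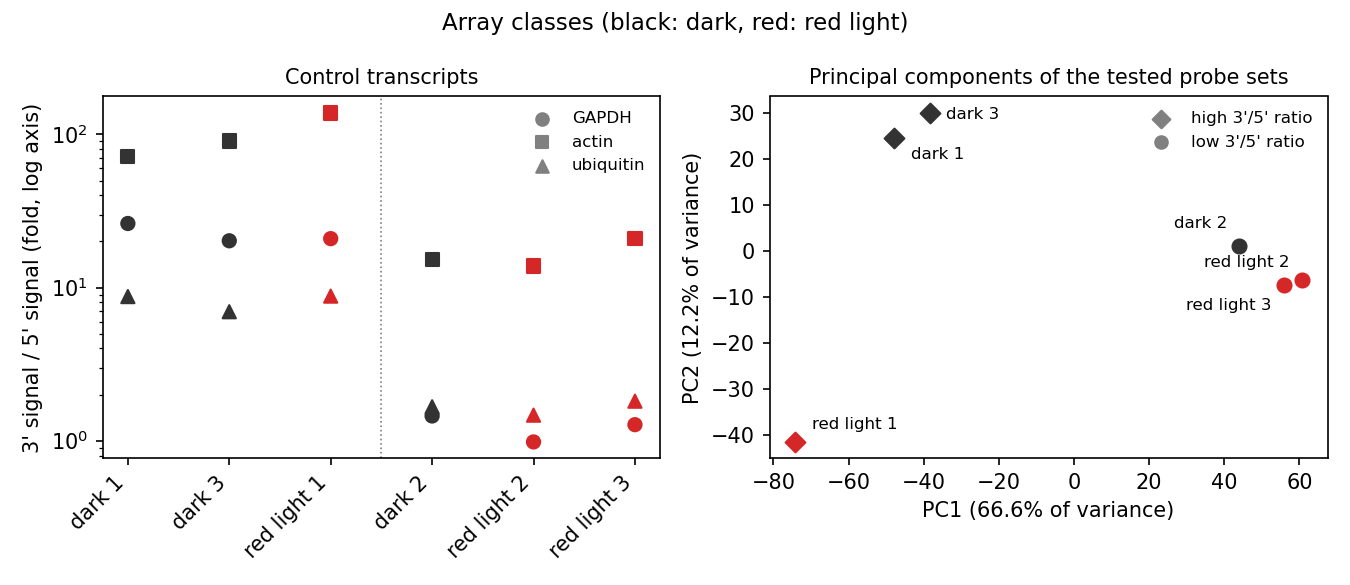
The left panel shows the 3'/5' signal ratio (fold, log axis) of GAPDH, actin and ubiquitin for each of the 6 arrays, and the right panel the arrays on the first principal components of the tested probe sets, with 66.6% and 12.2% of the variance. Dark 1, dark 3 and red light 1 lie apart from dark 2, red light 2 and red light 3 in both, with dark arrays in black and red light arrays in red.

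None of the genes with the smallest p by group alone passed the test. UGT78D2, a flavonoid glucosyltransferase and the tested member of the flavonoid list, had a change of 1.25 (SE 0.30), with signals of 89.6 to 126.8 in the dark and 250.2 to 268.7 in red light. The chloroplast ribosomal protein gene rpl32 had a change of 1.57 (SE 0.44). AT2G16365, AT2G36290 and AT5G62440 had changes of 2.04 (SE 0.44), 1.08 (SE 0.30) and 1.20 (SE 0.34). AT2G25450, a dioxygenase gene of glucosinolate metabolism, had a change of -2.23 (SE 0.43), which was -1.19 in the high-ratio class and -3.18 in the low-ratio class. HRGP1, a hydroxyproline-rich glycoprotein of the cell wall, had a change of -1.28 (SE 0.29), on a probe set whose name marks it as open to cross-hybridisation. AT2G25510, AT1G29020, AT1G12400 and AT3G07600 had changes of -2.83 (SE 0.58), -1.28 (SE 0.29), -2.44 (SE 0.65) and -1.15 (SE 0.31). The remaining genes of this set, psaB, AT1G13670, AT3G02910, AT5G23830 and ZW9, are those called with array class. With array class in the fit, AT1G29020 and HRGP1 both had a limma adjusted p of 0.0637.

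Of the 26 circadian clock genes listed, 2 were tested through named probe sets. The others had no named probe set, so whether they responded could not be told. GI (GIGANTEA) had a change of 0.84 (SE 0.25, limma adjusted p = 0.999), with signals of 895.7 to 1056.1 in the dark and 1510.7 to 2003.5 in red light. Its change was 0.71 in the high-ratio class and 0.80 in the low-ratio class. The MYB-like gene RVE6 had a change of 0.26 (SE 0.60), which was -0.22 (SE 0.31) with array class.

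No gene list passed its test by group alone, with camera adjusted p-values of 0.842 to 0.869, estimated-correlation adjusted p = 0.926 and fry adjusted p = 0.942 for each of the 6 lists. No member was called over all probe sets or adjusted over the list alone. The 6 tested nuclear photosynthesis genes had a median change of -0.06, and their signal differed between the classes by a median of 1.25. Among them, the antenna protein gene LHCB4.1 had a change of -0.33 (SE 0.29) and the Rubisco activase gene RCA of 0.32 (SE 0.57). The median of the 5 chlorophyll and haem genes was -0.07, with GSA1 at -0.25 (SE 0.29) and CHLM at 0.17 (SE 0.29). The median of the 5 auxin response genes was -0.05, with GH3.3 at -0.61 (SE 0.51) and IAA30 at -0.19 (SE 0.46).

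The 3 gibberellin receptor genes had a median change of -0.55, with GID1A at 0.59 (SE 0.66) and GID1C at -0.55 (SE 0.64). GID1B, named after its values were seen, had a change of -0.70 (SE 1.71), with a signal of 6.9 in red light 1. The median was -1.80 in the high-ratio class, where red light 1 is the only red light array, and 0.15 in the low-ratio class. It was -0.058 with the pseudocount, 1.45 with array weights and 1.23 without red light 1. The 9 cell wall genes of the XTH and expansin families had a median of -0.10, but a mean of 0.12, the sign of the camera test. The expansin gene EXPA4 had a change of 2.00 (SE 0.99), which was 1.08 (SE 0.29) with array class, and XTH20 had a change of -0.49 (SE 0.53). EXPA4 differed between the classes by -2.75, more than between the treatments.

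The 3 root hair markers, the expansin genes EXPA7 and EXPA18 and the wall enzyme gene XTH26, all 3 also in the cell wall list, had a median change of -0.34 by group alone. With array class in the fit their median was -0.999, all 3 lay below 0, and 2 of 3 were called when adjusted over the list alone, but 0 over all probe sets. The list then passed in limma's camera with an adjusted p of 0.00591, and had an adjusted p = 0.545 with an estimated correlation. The median was -1.84 in the high-ratio class, where red light 1 is the only red light array, and -0.16 in the low-ratio class. That difference was not tested. In the same order, XTH26 changed by -1.15 and -0.47, EXPA7 by -3.19 and 0.11, and EXPA18 by -1.84 and -0.16. EXPA7 had signals of 16.6 in red light 1 and of 139.6 and 164.5 in the dark arrays of the high-ratio class. Without red light 1 the median by group alone was 0.92. The markers also differed between the classes by a median of -2.47.

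Of genes known to answer handling, ZAT10 had a change of -0.77 (SE 0.43) and WRKY53 of -0.28 (SE 0.41). The heat-induced immunophilin gene ROF2 had a change of 0.10 (SE 0.54), and EIN3, a transcription factor of ethylene signalling, of -0.12 (SE 0.24). None of the 4 was called in either fit.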

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

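Of the tests in this part, those with array class in the fit, the gap in actin and ubiquitin ratios, the share of probe sets that differ between the classes and the class difference of chloroplast-encoded genes were chosen after the result was seen. The added GAPDH ratio was chosen after the classes were seen but before its own result, the added actin and ubiquitin ratios also after the GAPDH result, and the test on shoot tissue before its result.

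A control probe set for the large ribosomal RNA, which enters no comparison, had a signal of 1376.8 in red light 3, against at most 122.9 in the dark arrays and 89.3 and 119.7 in the other red light arrays. The control for 5S ribosomal RNA instead followed array class. Its signal was 746.2, 277.1 and 2074.7 in dark 1, red light 1 and dark 3, against 61.7, 36.3 and 64.4 in dark 2, red light 2 and red light 3.

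The first pattern is the split of the 6 arrays into classes that cross the treatment. Red light is argued against as its source, because with group in the fit 36.8% of the tested probe sets still differed between the classes. A target that reaches less far towards the 5' end in the high-ratio class is a candidate explanation, since actin and ubiquitin, which did not define the classes, both separated them with a smallest gap of 1.78 in log2 ratio. Shoot tissue in 1 class stays open, with values on both sides. The 6 measured nuclear photosynthesis genes differed by a median of 1.25 (SE 0.39 over genes), or 1.03 (SE 0.57 over arrays) as array means. The bound was 1.12, the median absolute class difference of the probe sets that differed between the classes. The median lay above this bound, and the array means lay below it by less than their standard error. Among these genes, PSBW differed by 2.24 (SE 0.40), PSAE1 by 1.64 (SE 0.78), PSAN by 1.37 (SE 0.27) and PSBY by 1.12 (SE 0.47). Against shoot tissue, LHCB4.1 (signals of 374.8 to 641.1) differed by -0.036 (SE 0.25) and RCA (67.4 to 259.5) by -0.15 (SE 0.56). The 43 chloroplast-encoded genes differed by a median of -0.042, or -0.11 (SE 0.69 over arrays) as array means.

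The next pattern is the set of 17 probe sets called with array class, psaB and AT5G23830 among them. A remaining 3' bias within the classes stays open. Adding the GAPDH, actin or ubiquitin ratio beside array class kept 92.9%, 96.0% and 101.5% of the median absolute change of the 17. They had been called for changes that were large against their residuals in the fit with array class. An added covariate could therefore hardly move these changes, and the kept shares decide nothing. Only 6, 6 and 15 of the 17 stayed called in these fits, each with 1 residual degree of freedom fewer. The cause of the losses was not tested. Only 1 of 9 splits that keep the classes gave as many calls, the real one with 17 against at most 1 in the others, and 9 splits are too few for a share under 0.05. Treatment by red light stays among the open explanations and may account for these genes, as a hypothesis found and tested on the same arrays. By group alone the real split gave 0 calls, so that all 10 splits of the arrays into 3 and 3 reach that count by definition and it tests nothing, while the split that follows array class gave 5070.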

How the results depend on the processing

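The fits with array class, with the GAPDH ratio and with the low-ratio class alone were chosen after the data were seen. By group alone the count of calls stayed at 0 under both scalings, the pseudocount, both filters, plain eBayes and both other thresholds. It was 2261 with array weights (1311 higher, 950 lower), 17 with array class (11 higher, 6 lower), 22 with the ratio as a covariate (14 higher, 8 lower) and 272 in the low-ratio class alone (119 higher, 153 lower), where the lone dark array is assumed to vary like the red light arrays. Leaving out 1 array gave 0 to 10 calls, with 10 without red light 1. The weights were lowest for red light 1 (0.20) and dark 2 (0.39), the arrays whose class holds mostly the other treatment. Of the 2261 calls, 81.6% differed between the classes, against 36.8% of all probe sets tested, and 13 were called with weights and array class together.

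All of the 17 probe sets called with array class that were still tested kept their direction in every alternative. Over the 8 named genes, the call stood in 94 combinations of gene and alternative and was lost in 47. Their number was 28 with quantile scaling (18 higher, 10 lower), 30 with the pseudocount (17 higher, 13 lower), 5 with plain eBayes, 7, 9 and 23 with the GAPDH, actin or ubiquitin ratio added, and 38 at an adjusted p of 0.1. Leaving out 1 array gave 8 to 272 calls. There were 8 without red light 2, 9 without red light 3, 28 without dark 3 and 71 without red light 1. The 272 came without dark 2, when red light 1 alone is compared with dark arrays of its own class. The cause was not tested.

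Whether replicate numbers mark pairs could not be told. Deviations from the group means correlated across probe sets at 0.58, 0.64 and -0.32 for numbers 1, 2 and 3. The arrays of numbers 1 and 2 each share an array class, whereas those of number 3 do not, so these values follow class. Not every array correlated best with its own number. With the replicate number as a block, 0 probe sets were called by group alone, and 17 with array class, 12 of them among the 17 called without the block. That last fit takes the red light change from numbers 1 and 2 only, since the class term takes up the difference in number 3.

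The number of lists that passed was 0 by group alone, 1 with array class and 2 with the ratio. Root hair markers had medians of -0.999 and -1.17 in these fits, past the threshold, and gibberellin receptors -1.15 with the ratio (camera adjusted p = 0.0424, and 0.124 with array class). With an estimated correlation no list passed, with adjusted p = 0.545 for both lists with array class and 0.430 for both with the ratio. Directions reversed as follows, and the cause was not tested. With array weights the medians were 1.45 (gibberellin), 0.55 (cell wall) and 1.08 (root hair), and CHLM was at -0.10, GID1C 0.19, ROF2 -0.52, XTH26 0.21, EXPA7 1.63 and EXPA18 1.08. With array class, nuclear photosynthesis was at 0.26, RVE6 -0.22 and IAA30 0.10. With the ratio, nuclear photosynthesis was at 0.32, RVE6 -0.33, IAA30 0.14, GID1A -0.11 and WRKY53 0.015. In the low-ratio class alone the gibberellin median was 0.15, RCA -0.50, IAA30 0.12, WRKY53 0.022 and EXPA7 0.11. Nuclear photosynthesis was at 0.022 without a filter, and the cell wall median and EXPA7 at 0.014 with the pseudocount.

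With 1 array left out, medians ran from -0.58 to 0.40 for nuclear photosynthesis, -0.22 to 0.19 for chlorophyll and haem, -0.99 to 1.23 for gibberellin, -0.25 to 0.61 for cell wall and -0.80 to 0.92 for root hair. Changes ran from -0.28 to 0.65 for RCA, -0.043 to 0.35 for CHLM, -0.13 to 0.85 for RVE6, -0.49 to 0.14 for IAA30 and -0.99 to 0.19 for GID1C. They ran from -0.41 to 0.48 for ROF2, -0.70 to 0.063 for XTH26, -1.25 to 1.41 for EXPA7 and -0.80 to 0.92 for EXPA18. The highest medians of the gibberellin, cell wall and root hair lists came without red light 1. None of the reversed values passed the threshold. Dim probe sets limit the rest, since a signal under 88.4 was not tested.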

Other observations

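The tests on gene families, on the chloroplast-encoded genes, on differences per array and on shoot tissue in the red light samples were chosen after the data were seen, while the comparison with mitochondrial genes and the splits were set before their results.

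Chloroplast-encoded genes lay higher in red light as a group. Of 43 tested genes of the chloroplast genome, 37 had a change above 0 by group alone, with a median of 0.79, and 38 with array class, with a median of 0.92. In limma's camera the adjusted p over 15 families was 8.48e-13 by group alone and 6.53e-11 with array class. With an estimated correlation, camera gave an unadjusted p = 0.0847 by group alone. With array class it gave an unadjusted p = 0.178 and an adjusted p = 0.914, so the call is lost. The median was 0.92 with quantile scaling and 0.74 with scaling to the 75th percentile. All 3 red light arrays lay above all 3 dark arrays for psaB, rpl32, petA and the ATP synthase gene atpE. These 4 genes were singled out after their values were seen, and only psaB was called. The shift was not shared by both classes, since the median was 1.80 in the low-ratio class and -0.16 in the high-ratio class, a difference that was not tested. In the same order, the medians were 1.23 and -0.051 for the 11 mitochondrially encoded genes and -0.33 and 0.83 for the 6 nuclear photosynthesis genes, all 6 of which lay between -0.50 and 0.29 in the low-ratio class. The median signal of the 43 genes was 246.2, 188.4 and 492.7 in dark 1, 2 and 3, and 221.4, 692.7 and 602.3 in red light 1, 2 and 3. The median change was 1.34 without red light 1, 1.305 without dark 3 and 0.59 without dark 2. The mitochondrial median was then 0.054, 0.59 and -0.19, and the nuclear one -0.58, 0.25 and -0.37.

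The last pattern weighed is this shift of the chloroplast genes, and more organelle RNA in the red light targets stays open as its source. The mitochondrially encoded genes had medians of 0.28 by group alone and 0.69 with array class, and per array the chloroplast genes exceeded them by 0.59 (SE 0.55 over arrays) and 0.24 (SE 0.28). Shoot tissue in the red light samples is not excluded either, as the chloroplast genes exceeded the nuclear ones (medians of -0.062 and 0.26) per array by 1.05 (SE 0.91) and 0.67 (SE 0.90), although the opposite split of the nuclear genes by class goes against it as the whole source. The bounds set for both, on spread over genes, were exceeded in both fits, but genes on the same arrays are no replicates, and each class compares 1 array with 2. Of the 10 splits of the arrays, 2 gave a median difference as large, with 0.79 for the real split and 1.43 for the highest other, and 10 splits are too few for a share under 0.05.

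The 8 tested ATG genes of autophagy, mostly of the ATG8 group, all had changes below 0 in both fits, with a median of -0.62 by group alone and -0.25 with array class. Within the high-ratio class ATG8F (0.35), ATG8B (0.22), ATG8H (0.16) and ATG8D (0.033) lay above 0, and ATG8C, ATG8E, ATG8G and ATG3 below. Within the low-ratio class all 8 lay below 0. In limma's camera their adjusted p was 0.0031 by group alone and 0.162 with array class. With an estimated correlation, camera gave an unadjusted p = 0.145 by group alone. They were higher in the high-ratio class by a median of 1.13. Under quantile and 75th percentile scaling the median was -0.63 and -0.67. The largest member change was that of ATG8G, -0.99 (SE 0.52), and none was called. The median was -0.28 without red light 3, -0.32 without dark 1, -0.40 without red light 2 and -0.96 without red light 1.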
